A study of Mus musculus with 4 samples.

How the data were processed

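RNA from unstimulated LPC-HRas mouse liver cancer cells was measured in 4 libraries, 2 from control cells and 2 from cells overexpressing UBXN9, the product of Aspscr1. Libraries were made with the TruSeq RNA kit, which selects poly-A RNA, and sequenced on an Illumina HiSeq instrument. The deposited table holds estimated counts of fragments per gene, not scaled to a common total; the authors' processing notes name HISAT2 2.1.0, HTSeq and the build GRCm38.p6. The settings, the annotation and the handling of strand and of overlapping genes are not stated there. Some values are fractions, and 241 of the 55728 entries are loci outside the annotation, so values were rounded to whole counts and these loci were kept out of the main comparison. Of the 55487 annotated identifiers, 55227 were found in GENCODE release M21 (GRCm38), which gave positions, types and overlaps, and 55141 had a symbol.

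Totals per library ran from 21814969 to 26292686 counts. Where a gene had 0 counts in both libraries of a group, its fold change is a bound against a floor of 3 counts over the group. Where the lower group held 1 to 3 counts, the ratio is given with an exact Clopper-Pearson 95% interval. Floors and intervals cover counting error only.

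Groups were compared with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter and quasi-likelihood F tests of the group term, two-sided. The 13230 genes left were adjusted together by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as a change. Levels are CPM scaled with the TMM factors. Gene lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists with at least 3 tested members. Fry tests whether the genes of a set move on balance one way and does not compare them with other genes. Reactome sets with 10 to 300 tested members came from fgsea 1.28.0. Figures were drawn with matplotlib 3.10.9.

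The gene lists, the comparison, its test, the rule for named genes and most alternatives were fixed before the data were examined. The 35 lists were interferon-stimulated genes, nucleic acid sensing, MHC class I presentation, cytokines and chemokines, NF-kB targets, immune ligands, RNA exosome and cofactors, small nucleolar RNA host genes, replication histones, cell cycle, p53 targets, endoplasmic reticulum chaperones, ATF4 targets, VCP and UBX cofactors, glycolysis and glucose transport, hypoxia, cholesterol synthesis, fatty acid synthesis, RAS and MAPK output, immediate early genes, heat shock, NRF2 targets, WNT targets, cell death, biliary and progenitor markers, hepatocyte genes, epithelial junction genes, matrix and mesenchymal genes, ribosomal proteins, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, and lymphoid, myeloid, endothelial, and stellate and fibroblast markers. Some genes are on more than 1 list. Named genes were Aspscr1; among genes with an adjusted p under 0.05, at least 2 CPM in the higher group and both UBXN9 libraries on the same side of both controls, the 10 with the largest change in each direction; up to 4 members with the smallest p of each list that camera called or that held at least 3 called members, and up to 2 of each other list; Ifnb1, Isg15, Cxcl10, Ddx58, Ifih1, Mavs, B2m, Cd274, Exosc10, Dis3, Mtrex, Hras and Vcp; and up to 2 members of the 5 Reactome sets with the smallest p in each direction. Ifng, Ifna2 and Lck, the RNAs without a poly-A tail, and the immune-cell transcripts were chosen after values had been seen.

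The procedure was tested on simulated data in 5 draws with 200 genes changed in each. Of genes changed by 1 on the log2 scale 44.4% were recovered, and of those changed by 2, 84.5%, with 7.6% of calls false. A list moved as a whole was called in 5 of 5 draws by camera, 0 with an estimated correlation and 2 by fry, and 0 of 500 unchanged lists were called by camera. Simulated genes varied independently of each other. These rates therefore cannot decide between the preset and the estimated correlation where genes vary together.

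The alternatives were RLE, upper-quartile and no composition factors, no filter, a filter of 5 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, a robust prior, a block for the replicate number, a 2-fold threshold, an adjusted p of 0.01, and leaving out each library in turn. With a library left out, the lone library of its group is assumed to vary like the other group. The median absolute log2 difference was 0.199 between the control libraries and 0.313 between the UBXN9 libraries. Fits without a UBXN9 library therefore rest on the pair that differed less. Added after the data were seen were a crossed replicate block, the unannotated loci, and leaving out chromosomes 4 and 8.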

Results

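RNA was sequenced from LPC-HRas cells, a mouse liver cancer cell line kept without stimulation, in 2 groups of 2 libraries each. The control group held libraries control 1 and control 2, and the other group held UBXN9-overexpressing 1 and 2, called UBXN9 1 and UBXN9 2 here. UBXN9 is a UBX-domain protein, encoded in the mouse by Aspscr1, of a family that binds the ATPase VCP. The total of estimated counts was 24677770 for control 1, 22147475 for control 2, 21814969 for UBXN9 1 and 26292686 for UBXN9 2. Levels are given as CPM, counts scaled to a common library total with TMM factors, as the mean and SD over the n = 2 libraries of a group.

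The comparison of UBXN9-overexpressing with control cells asked which genes differ when UBXN9 is raised. Aspscr1 itself (ENSMUSG00000025142, chromosome 11, 120672973 to 120709447, GRCm38) had 104 ± 16.3 CPM in control and 386 ± 8.22 CPM in UBXN9-overexpressing cells (SD, n = 2). Its log2 fold change was 1.90 with an SE of 0.18, a 3.72-fold rise (edgeR adjusted p = 0.00144), and Gm17178 overlaps it. Of 57 interferon-stimulated genes tested 53 rose, and of 20 genes of antigen presentation on MHC class I 17 rose. Camera called both lists, but with an estimated correlation the adjusted p was 0.261 for each. Fry, which does not compare a list with other genes, gave adjusted p values of 0.0134 and 0.0372. Of 13230 genes tested with edgeR, 984 changed, 669 higher and 315 lower. In all 984 both UBXN9 libraries lay on the same side of both controls, as they did in 50.6% of all genes tested, against 33.3% by chance. A change of at least 2-fold was found in 788 of them, and 164 rose and 45 fell by at least 8-fold. Leaving out control 2 gave 508 changed genes (373 higher, 135 lower), while leaving out UBXN9 1 gave 2561 (1611 and 950) and leaving out UBXN9 2 gave 2782 (1464 and 1318). Without control 1 the count was 702 (507 and 195). The p-values measure only the spread between these libraries, and an exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.333.

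Libraries of a group also differed from each other. The first principal component, with 70.4% of the variance, separated the groups, and the second, with 22.2%, separated mostly UBXN9 1 from UBXN9 2. Across genes, which are not independent replicates, the difference between the control libraries had a Spearman correlation of -0.366 with transcript length, and that between the UBXN9 libraries 0.476. The difference between the groups had a correlation of -0.0138. Ribosomal RNA from the gene CT010467.1 (chromosome 17, 39846353 to 39848827) took 0.211% and 0.342% of the counts in control 1 and 2, against 0.511% and 0.824% in UBXN9 1 and 2, with an adjusted p of 0.0626. Rn7sk, the 7SK RNA that carries no poly-A tail, stood at 1.68, 2.31, 5.48 and 26.4 CPM in the same order of libraries. Its log2 fold change was 3.01 (edgeR adjusted p = 0.0488). Rn7s1 and Rpph1, also without a poly-A tail, had log2 fold changes of 3.31 and 3.14 and did not pass (edgeR adjusted p = 0.101 and 0.0751).

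Of 57 interferon-stimulated genes tested, 53 rose and 0 fell, with a median log2 fold change of 2.49, and adjusted over the list alone 56 rose. The list was called by camera (adjusted p = 1.83e-166), and the adjusted p was 0.261 with an estimated correlation. Parp12, an ADP-ribosyltransferase, rose from 8.0 ± 0.625 to 203 ± 14.6 CPM, a 25.5-fold change (log2 4.67, SE 0.18, adjusted p = 0.00022). Phf11d rose 30.5-fold, Gbp2, an interferon-induced GTPase, rose 16.4-fold, and the nuclear body gene Sp100 rose 55.8-fold, each with an adjusted p of 0.00022. Isg15, a ubiquitin-like modifier that was already abundant in control cells, rose from 377 ± 14.6 to 1391 ± 304 CPM, a 3.69-fold change. Ifi27, with a log2 fold change of -0.25, was the member with a negative value, and it did not pass the test. The other members not passing were Slfn8, Eif2ak2 and Samd9l, which like Ifi27 were named after their values were seen.

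Genes that sense foreign or misplaced nucleic acid showed 10 of 23 tested members higher and 0 lower, with a median log2 fold change of 0.81; adjusted over the list alone, 13 were higher and 1 lower. Without members on chromosomes 4 and 8 the median was 0.52. The camera adjusted p was 6.19e-11, and the adjusted p was 0.261 with an estimated correlation. Zbp1, a sensor of Z-form nucleic acid that is also on the interferon list, rose 23.9-fold from 19.2 ± 1.5 to 457 ± 84.7 CPM. Tlr3, the endosomal receptor of double-stranded RNA, rose 16.5-fold, and Dhx58 5.60-fold. The RNA sensors Ifih1 and Ddx58 rose 4.10-fold (SE of the log2 change 0.23) and 2.80-fold (SE 0.19). Mavs, their shared adaptor, had 52.7 ± 0.129 CPM in control and 44.0 ± 8.41 CPM in UBXN9-overexpressing cells and did not pass (adjusted p = 0.49).

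Ifnb1, the gene for interferon beta (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774), had 2 and 5 counts in the controls and 28 and 45 in the UBXN9 libraries. Its log2 fold change was 3.35 with an SE of 0.61 (adjusted p = 0.0206), and it was 2.74 without control 1 (adjusted p = 0.109) and 4.25 without control 2. Ifng had 1 count in control 1 and 0 in the other libraries, and Ifna2 had 3 counts in each UBXN9 library and 0 in the controls. Neither was deep enough to test.

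**Figure D1:**
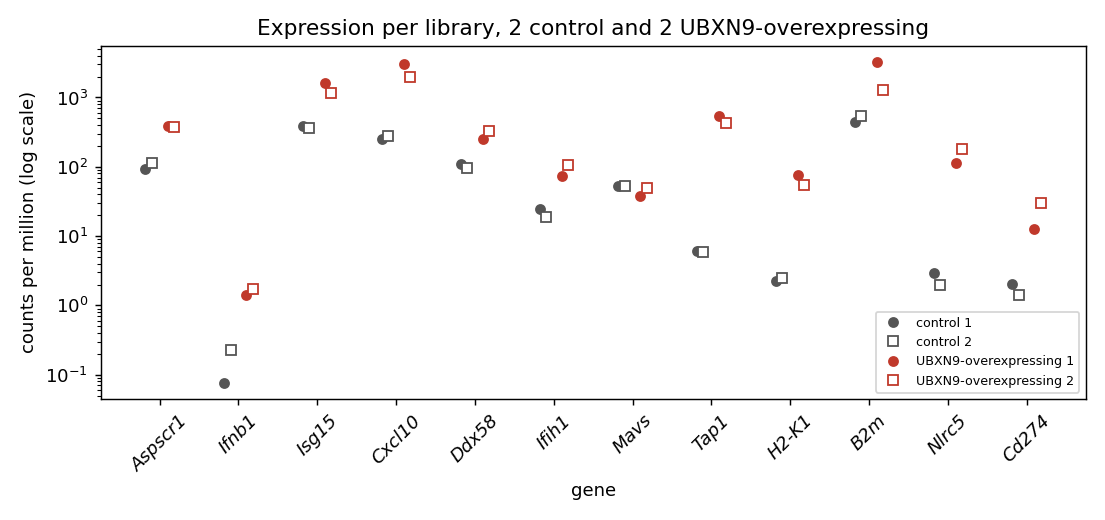
Level in CPM on a log axis for 12 genes in each of the 4 libraries; filled circles are replicate 1, open squares replicate 2, grey control and red UBXN9-overexpressing. Tap1 rose from 5.98 to 480 CPM in the mean, while Mavs stood at 52.7 and 44.0 CPM.

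Antigen presentation on MHC class I, which shows peptides on the cell surface, had 17 of 20 tested genes higher and 0 lower, with a median log2 fold change of 2.16; adjusted over the list alone, 17 were higher. Camera gave an adjusted p of 1.8e-55, and the adjusted p was 0.261 with an estimated correlation. Tap1, the peptide transporter (ENSMUSG00000037321, chromosome 17, 34187553 to 34197225), rose from 5.98 ± 0.238 to 480 ± 73.9 CPM, with a log2 fold change of 6.33, an SE of 0.22 and an adjusted p of 0.00022. Psmb9, an immunoproteasome subunit whose annotation overlaps Tap1, rose from 0.293 to 83.3 CPM, with a log2 fold change of 8.05 that was 9.75 without control 1 and 7.38 without control 2. The heavy chain gene H2-K1 rose 27.9-fold, H2-D1 9.54-fold, and Nlrc5, a transactivator of class I genes, 58.5-fold. Heavy chain genes are close copies of each other, so reads split between them are uncertain. B2m, the light chain, rose 4.62-fold (SE of the log2 change 0.43) from 488 ± 69.6 to 2255 ± 1406 CPM, with 3249 CPM in UBXN9 1 and 1261 CPM in UBXN9 2; without UBXN9 1 the rise was 2.59-fold.

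Cytokine and chemokine genes had 13 of 27 tested members higher and 0 lower, with a median log2 fold change of 0.85; adjusted over the list alone, 18 were higher. The camera adjusted p was 7.57e-13, and the adjusted p was 0.261 with an estimated correlation. Cxcl10, a chemokine that attracts T cells, rose 9.40-fold from 266 ± 14.7 to 2497 ± 783 CPM. Its relatives Cxcl9 and Cxcl11 rose 59.6-fold and 11.1-fold from below 1 CPM, and the neutrophil attractant Cxcl5 rose 3.58-fold. Ligands and enzymes that restrain or guide immune cells had 4 of 10 higher and 0 lower (median log2 fold change 0.38, and 0.16 without members on chromosomes 4 and 8), and adjusted over the list alone 5 were higher and 2 lower. Camera gave an adjusted p of 0.00354, the adjusted p was 0.311 with an estimated correlation, and it was 0.0723 without genes of chromosomes 4 and 8. Cd274, which encodes PD-L1, rose 12.3-fold to 21.4 ± 12.1 CPM (SE of the log2 change 0.46), and 7.33-fold without UBXN9 2. Ido1, a tryptophan-degrading enzyme, rose 38.4-fold to 4.19 CPM (24.1-fold without UBXN9 1) and lies on chromosome 8, and Lgals9, which encodes galectin-9, rose 3.83-fold.

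Cell death genes had 6 of 25 members higher and 0 lower, with a median log2 fold change of 0.20, and the same 6 higher and 0 lower counts adjusted over the list alone. The camera adjusted p was 0.00481, and the adjusted p was 0.311 with an estimated correlation. Mlkl and Ripk3, of the necroptosis pathway, rose 3.29-fold and 6.31-fold. Casp1, the inflammasome caspase, rose 14.8-fold from 4 counts in both controls together, with an adjusted p of 0.103 without control 2 and a 25.4-fold rise without control 1. NF-kB target genes had 4 of 18 higher and 0 lower (median log2 fold change 0.33), and adjusted over the list alone 5 were higher. Camera gave an adjusted p of 8.08e-05, and the adjusted p was 0.289 with an estimated correlation. The adhesion gene Vcam1 rose 7.97-fold from 34.5 ± 5.84 to 275 ± 43.2 CPM. Icam1 rose 5.34-fold, with an adjusted p of 0.117 without control 2.

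Targets of ATF4, the transcription factor of the integrated stress response, had 5 of 25 members higher and 0 lower, with a median log2 fold change of 0.51; adjusted over the list alone, 10 were higher and 1 lower. The camera adjusted p was 0.000195, the adjusted p was 0.6 with an estimated correlation, and fry gave 0.0766. Chac1, a glutathione-degrading enzyme, rose 2.1-fold, with an adjusted p of 0.0689 without control 1 and 0.0835 without control 2. Ddit3, the transcription factor CHOP, rose 1.97-fold, with an adjusted p of 0.121 without control 1 and 0.103 without control 2. Immediate early genes had 5 of 17 higher and 0 lower (median log2 fold change 0.28, and -0.00475 without members on chromosomes 4 and 8), and adjusted over the list alone 8 were higher and 2 lower. Camera gave an adjusted p of 0.0311, and the adjusted p was 0.413 with an estimated correlation. The adjusted p of this list was 0.34 without genes of chromosomes 4 and 8, where 5 members lie, 0.055 without control 1, 0.125 without UBXN9 1 and 0.0585 with a replicate block. Egr1, a growth factor response gene, rose 2.62-fold, and Klf4, on chromosome 4, rose 2.12-fold, with an adjusted p of 0.12 without control 2.

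**Figure D2:**
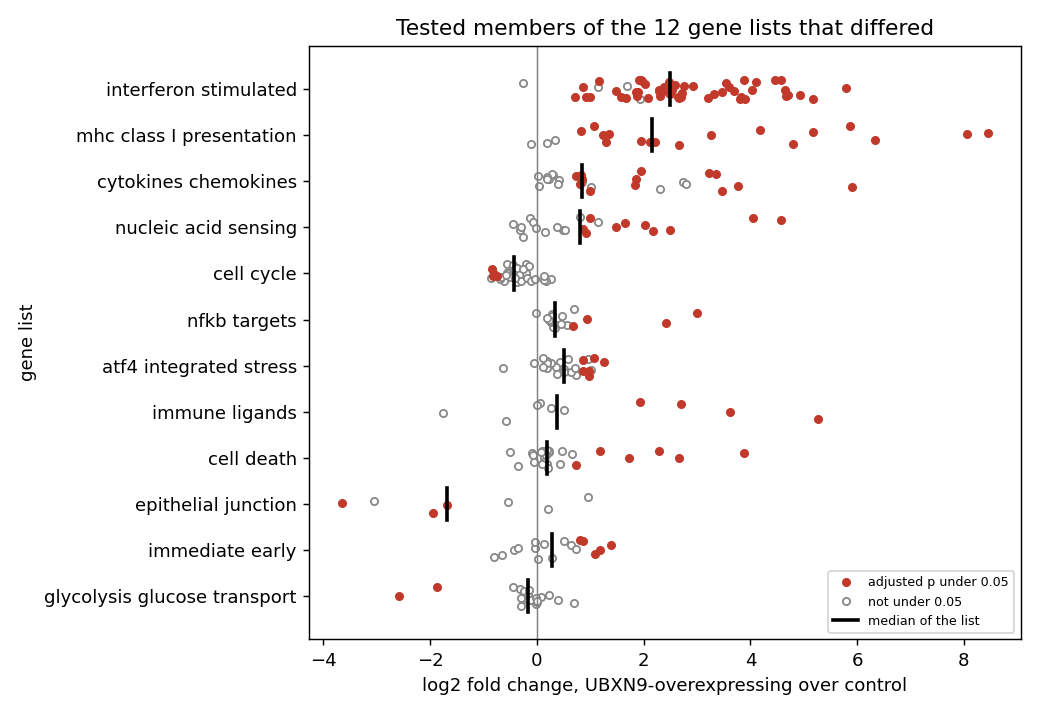
Log2 fold change of each tested member of the 12 lists that camera called, with red points for members with an adjusted p under 0.05, open points for the others and a black bar at the median of the list. The interferon-stimulated list has its median at 2.49 and the cell cycle list at -0.421.

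Cell cycle genes fell as a list. Of 37 tested, 4 fell and 0 rose, 33 had a negative log2 fold change, and the median was -0.42; adjusted over the list alone, 5 fell. The camera adjusted p was 1.63e-05, and the adjusted p was 0.311 with an estimated correlation. Kif20a, a kinesin of cytokinesis, fell by 0.85 on the log2 scale (SE 0.16, adjusted p = 0.0214), and Aurkb, a mitotic kinase, fell by 0.83 (SE 0.15, adjusted p = 0.0214). The adjusted p of Kif20a was 0.0861 without control 1, 0.212 without control 2 and 0.0523 with a replicate block, and that of Aurkb was 0.105, 0.227 and 0.0547. Rrm2 and Birc5 were the other called members, and their calls were lost in the same settings, with adjusted p values of 0.13, 0.243 and 0.0728 for Rrm2 and 0.233, 0.259 and 0.0963 for Birc5.

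Epithelial junction and keratin genes had 3 of 7 tested members lower and 0 higher. The median log2 fold change of the tested members was -1.69 (-1.13 without control 1 and -1.05 without control 2). Adjusted over the list alone, 4 were lower. The list holds 19 genes, and those not tested, Cdh1 among them, had at most 14 counts in any library. Camera gave an adjusted p of 0.0132, and the adjusted p was 0.532 with an estimated correlation. The adjusted p of the list was 0.0528 without control 2, 0.0567 without UBXN9 1, 0.133 without UBXN9 2, and 0.0644 by fry. The keratin gene Krt18 fell from 2.83 ± 0.229 to 0.231 ± 0.166 CPM (log2 fold change -3.66, and -4.58 and -3.0 without UBXN9 1 and 2), and Krt19, another keratin gene, fell from 8.72 ± 2.36 to 2.72 ± 0.803 CPM, with an adjusted p of 0.143 without control 2. Elf3, an epithelial transcription factor, fell by 1.94 on the log2 scale, with an adjusted p of 0.0679 without control 1, 0.328 without control 2 and 0.0673 by DESeq2. The list of glycolysis and glucose transport had 2 of 20 lower and 0 higher, also when adjusted over the list alone, with a median of -0.16. The median was -0.31 without control 1, -0.045 without control 2, -0.30 without UBXN9 1 and -0.035 without UBXN9 2. Camera gave an adjusted p of 0.0429, and the adjusted p was 0.833 with an estimated correlation, 0.21 without control 2, 0.203 without UBXN9 2 and 0.299 by fry. Both called members are transporters rather than glycolytic enzymes. Slc16a3, a lactate exporter, fell from 98.3 ± 14.8 to 16.5 ± 3.38 CPM, and Slc2a3, a glucose transporter, from 47.5 ± 6.27 to 13.0 ± 0.634 CPM.

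Counts of called members within the lists depended on which library was left out, and so on which pair of libraries gave the spread. Cell cycle genes had 0 lower without either control, 11 lower without UBXN9 1 and 16 lower without UBXN9 2, and ATF4 targets had 0, 1, 8 and 12 higher without control 1, control 2, UBXN9 1 and UBXN9 2. In the same order cytokine and chemokine genes had 7, 7, 17 and 16 higher, NF-kB targets 2, 1, 6 and 6, and immediate early genes 3, 1, 7 and 8. Cell death genes had 3 higher and sensing genes 7 higher without control 2. Epithelial genes had 2 lower without control 1 and 1 lower without control 2. The interferon-stimulated list had between 49 and 56 higher, and antigen presentation between 14 and 18. Immune ligands had 0 lower without control 1, 1 lower without control 2 and 2 lower without either UBXN9 library. RAS and MAPK output genes had 4 higher and 3 lower without UBXN9 2, VCP and its cofactors 4 higher without UBXN9 1 and 3 without UBXN9 2, and RNA exosome genes 2 higher and 3 lower without UBXN9 1 and 1 higher and 3 lower without UBXN9 2. Biliary markers had 1 lower without control 2, and p53 targets had 4 higher and 3 lower without UBXN9 1. Nuclear genes of oxidative phosphorylation had 6 lower without UBXN9 1 and 5 higher and 1 lower without UBXN9 2, and cholesterol synthesis genes had 5 higher and 1 lower without UBXN9 2. Mitochondrially encoded genes had 3 lower and 0 higher without UBXN9 1 but 3 higher and 1 lower without UBXN9 2. Replication histones had 4 of 32 higher without UBXN9 1 and 2 of 21 without UBXN9 2, with medians of 0.73 and 0.11 against 0.21 with all libraries. WNT targets had 2 lower without either UBXN9 library, NRF2 targets 1 higher without either control and 3 higher without either UBXN9 library, and heat shock genes 2 lower without UBXN9 2. The median was 0.59 for immune ligands without UBXN9 1, 0.18 for immediate early genes without control 1, and 0.027 for p53 targets without control 1. For ribosomal protein genes it was -0.26 without UBXN9 1 and 0.22 without UBXN9 2, and for hypoxia genes -0.084 and 0.12.

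The largest rises included genes listed at 0 in both control libraries, for which a bound is given against a floor of 3 counts over the group. The pseudogene Gm7609 was at least 129-fold higher and ENSMUSG00000118590 at least 71.3-fold. Sp110, a relative of Sp100, was at least 65.2-fold higher, the B cell transcription factor Pax5 at least 60.2-fold and Trim30c at least 40.6-fold. Psmb8, an immunoproteasome subunit, had 1 count in the controls and 414 in the UBXN9 libraries, a ratio of 429 (95% exact interval 76.5 to 17000, counting error only). Gbp4 had a ratio of 289 (79.6 to 2390) from 2 control counts and Ifi213 a ratio of 324 (57.7 to 12800) from 1. F830016B08Rik had a ratio of 214 (38.0 to 8500), with 22 counts in UBXN9 1 and 185 in UBXN9 2, and its adjusted p was 0.0574 with library size alone as the scaling. Pax5 had 2.44 CPM in UBXN9 1 and 5.05 CPM in UBXN9 2, and its bound was 39.2-fold without UBXN9 2. The fitted fold was 210 for Psmb8 and 94.6 for F830016B08Rik without control 2, and 130 for Ifi213 without control 1. When the other control was left out, the remaining one had 0 counts of the gene, so no fold is given. The fitted fold of F830016B08Rik was 272 without UBXN9 1 and 42.1 without UBXN9 2. Gbp4 overlaps Gbp8 and Gbp9, Psmb8 overlaps Gm20496, Pax5 overlaps Gm12462 and Sp110 overlaps G530012D18Rik, so their reads are not fully separable.

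Among the genes that fell most, Stac was listed at 0 in both UBXN9 libraries and was at least 107-fold lower. The pseudogenes Gm2260 and Gm2436, whose reads may be shared with their parent genes, were at least 63.0-fold and 38.3-fold lower. Wnt5a, a secreted WNT ligand, fell from 21.6 ± 5.71 to 0.439 ± 0.339 CPM (log2 fold change -5.54, SE 0.48, adjusted p = 0.001), and the log2 fold change was -6.73 without UBXN9 2. Car14, a carbonic anhydrase, fell from 17.0 ± 0.449 to 0.437 ± 0.0854 CPM, and Tmem159 from 4.69 to 0.0875 CPM. Bace2, a protease, had a log2 fold change of -4.95 (-6.06 and -4.20 without UBXN9 1 and 2), Dhrs4, a dehydrogenase, -4.71, and BC034090 -4.47. Car14 overlaps Aph1a, Wnt5a overlaps Gm2670, and Tmem159 overlaps 4930560O18Rik.

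RNA exosome genes and cofactors, the machinery of RNA decay from the 3' end, had 1 of 29 tested members lower and 0 higher, also when adjusted over the list alone, and the list did not pass camera (adjusted p = 0.656). Exosc10 had 104 ± 10.8 and 139 ± 4.80 CPM (adjusted p = 0.183), Dis3 33.9 ± 3.21 and 32.7 ± 6.03 CPM, and Mtrex 42.0 ± 3.28 and 41.7 ± 8.75 CPM. These 3 did not pass here, but with a crossed replicate block, chosen after the data were seen, Exosc10 had an adjusted p of 0.0152. Exosc6 (chromosome 8, 111056339 to 111057664) was listed at 0 in both UBXN9 libraries against 3.43 and 9.71 CPM in the controls, at least 102-fold lower, or 53.4-fold without control 2, but it overlaps Aars, so the counting of shared reads leaves this value uncertain. The list of VCP and its UBX cofactors had 1 of 18 higher and 0 lower, also when adjusted over the list alone, and did not pass camera (adjusted p = 0.351), while fry gave an adjusted p of 0.043 and an estimated correlation 0.643. Its median log2 fold change was 0.27, and -0.039 without members on chromosomes 4 and 8, where camera gave 0.871. Its 7 members on chromosomes 4 and 8 included the called one, Ubxn8 (1.91-fold), whose adjusted p was 0.319 without control 1, 0.257 without control 2 and 0.103 with a replicate block. Vcp, on chromosome 4, had 619 ± 30.1 and 799 ± 96.3 CPM (adjusted p = 0.308, and 0.0334 with the crossed replicate block). Hras, the oncogene this cell line is named for, had 68.1 ± 12.7 and 67.3 ± 18.0 CPM (adjusted p = 0.98). RAS and MAPK output genes had 1 of 21 higher, Egr1, and 1 lower, Areg, with an adjusted p of 0.718 by camera, 0.903 with an estimated correlation and 0.043 by fry, and 2 higher and 1 lower adjusted over the list alone; the adjusted p of Areg was 0.224 without control 2.

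Genes across chromosomes 4 and 8 were shifted upward. The median log2 fold change was 0.27 over 806 tested genes on chromosome 4 and 0.31 over 732 on chromosome 8. Chromosome 5 had 0.11, and the medians of the other autosomes lay between -0.09 and -0.01. Of the 984 changed genes, 62 higher and 7 lower lay on chromosome 4 and 65 higher and 8 lower on chromosome 8. Ifnb1, Isg15, Ddx58, Pax5, Klf4, Exosc10 and Vcp lie on chromosome 4, and Tlr3, Nlrc5, Ido1, Mlkl, Ubxn8 and Exosc6 on chromosome 8.

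**Figure D3:**
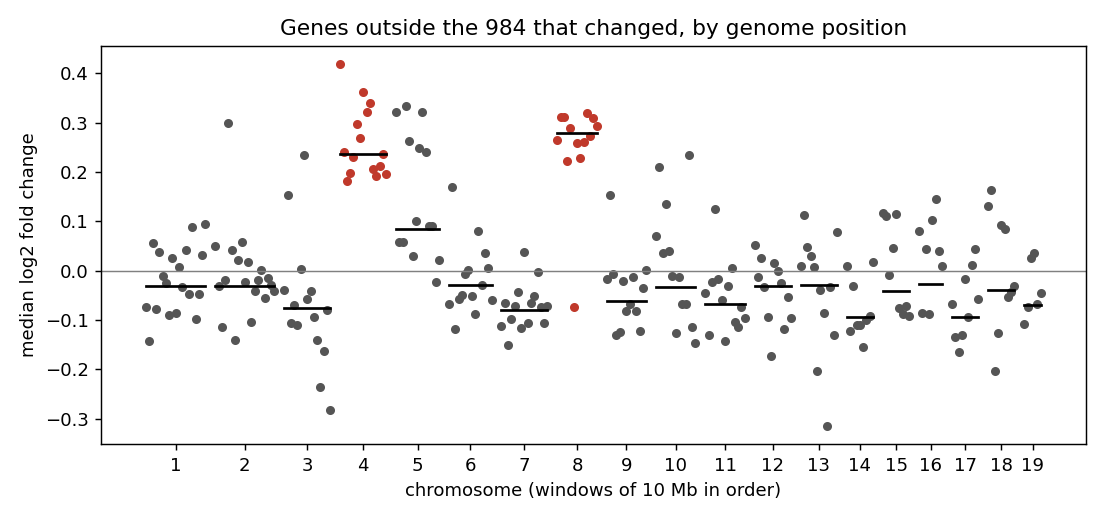
Median log2 fold change, UBXN9-overexpressing over control, of genes outside the 984 that changed, in windows of 10 Mb along each autosome, with a black bar at the median of each chromosome. Chromosomes 4 and 8, in red, have medians of 0.236 and 0.279.

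Lineage markers moved in both directions. Hepatocyte genes had 2 of 6 tested members higher and 1 lower (camera adjusted p = 0.0818); adjusted over the list alone, 4 were higher and 1 lower. The plasma protein genes Hp and Ahsg rose 3.54-fold and 5.03-fold, while Trf, which encodes transferrin, fell from 1034 ± 125 to 266 ± 40.9 CPM. Biliary and progenitor markers had 1 of 10 higher, Krt23, and 3 lower, Krt18, Cd24a and Krt19 (camera adjusted p = 0.229), the same counts as adjusted over the list alone, and the adjusted p of Cd24a was 0.0523 without control 2. Matrix and mesenchymal genes had 4 of 27 higher and 2 lower (camera adjusted p = 0.17), with adjusted p values of 0.0478 without control 1 and 0.0234 without UBXN9 1; adjusted over the list alone, 5 were higher and 3 lower. Its called members were 2 higher and 0 lower without either control, 6 and 3 without UBXN9 1, and 6 and 4 without UBXN9 2. Thbs1, which encodes thrombospondin 1, rose 9.19-fold and the collagen gene Col1a1 4.59-fold. Stellate and fibroblast markers had 2 of 9 higher, Col1a1 and Acta2, and 1 lower, Cygb, the same counts as adjusted over the list alone (camera adjusted p = 0.229).

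Markers of blood cells stayed low. Myeloid markers had 1 of 4 tested members higher, Lyz2, at 0.871 ± 0.333 and 3.11 ± 0.0314 CPM with an adjusted p of 0.0408, and 0.283 without control 2. The myeloid list did not pass (camera adjusted p = 0.28), but its adjusted p was 0.0303 without control 1, 0.0472 without control 2 and 0.00138 without UBXN9 2, where 6 of 9 tested members were higher. Of the lymphoid list only Lck was deep enough to test, with a log2 fold change of 1.05 (adjusted p = 0.0457, 1 of 1 adjusted over the list alone), a call lost without either control. Of 4 endothelial markers 0 passed by edgeR, DESeq2 or limma-voom and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.801). The immune-cell transcripts Ptprc, Tyrobp, Fcer1g, C1qa, C1qb, C1qc and Cd3e together came to 0.42 and 0.318 CPM in control 1 and 2 and to 5.53 and 0.452 CPM in UBXN9 1 and 2.

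The remaining lists did not pass camera, and their counts adjusted over the list alone are given last for each. Targets of p53 had 3 of 19 higher and 0 lower, with a median of -0.11, a mean of 0.09 and an adjusted p of 0.816 (4 higher, 1 lower); without either control 0 were called. NRF2 targets had 2 of 16 higher, Hmox1 (2.33-fold) and Osgin1, both on chromosome 8, and 0 lower (adjusted p = 0.28; 2 higher, 0 lower). Hypoxia genes had 1 of 13 lower, Egln3, and 0 higher, with a median of 0.0029, a mean of -0.05 and an adjusted p of 0.66 (1 higher, 2 lower). WNT targets had 1 of 8 higher, Notum (4.74-fold), and 0 lower (adjusted p = 0.753; 1 higher, 2 lower). Heat shock genes had 1 of 9 lower, Hspb1, and 0 higher (adjusted p = 0.753; 0 higher, 1 lower). Replication histones, whose RNA lacks a poly-A tail, had 1 of 22 higher, Hist2h2aa2, and 0 lower (adjusted p = 0.66; 1 higher, 0 lower), beside the ribosomal and 7SK RNA levels given above. Genes encoded on the mitochondrial genome had 1 of 15 lower, mt-Atp6, and 0 higher (adjusted p = 0.801; 0 higher, 1 lower). The calls of Osgin1, Hspb1 and mt-Atp6 were lost without either control, with adjusted p values, for control 1 and 2 in that order, of 0.159 and 0.113 for Osgin1, 0.184 and 0.22 for Hspb1, and 0.302 and 0.0553 for mt-Atp6. That of Egln3 was lost without control 2 (0.113).

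For 7 lists edgeR called 0 members, the endothelial list among them, and adjusted over the list alone it called 0 in each except fatty acid synthesis, with 1 higher. Ribosomal protein genes had 3 of 82 with an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom (camera adjusted p = 0.661, median -0.01, mean 0.0091), and this list was lower without UBXN9 1 (adjusted p = 0.000345) and higher without UBXN9 2 (adjusted p = 0.0445). Nuclear genes of oxidative phosphorylation had 5 of 71 with an unadjusted p under 0.05 and 1 called by DESeq2 (camera adjusted p = 0.229), and the list was lower without control 1 (adjusted p = 0.0205) and without UBXN9 1 (adjusted p = 0.000109). Cholesterol synthesis genes had 5 of 23 with an unadjusted p under 0.05 and 2 called by DESeq2 (camera adjusted p = 0.273). Fatty acid synthesis genes had 1 of 12 and 1 (0.913), chaperones of the endoplasmic reticulum 3 of 21 and 1 (0.344), and host genes of small nucleolar RNA 1 of 13 and 1 (0.753), given in the same order of unadjusted p, DESeq2 calls and camera adjusted p. Limma-voom called 0 in each of these 7 lists.

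Reactome pathway sets were tested beside the fixed lists. Of 795 sets tested, camera called 78, 62 higher and 16 lower. Among the higher sets, Interferon gamma signaling had 39 of 61 tested genes higher and 1 lower (adjusted p = 4.92e-48), with Sp100 and Gbp2 leading, and Antigen Presentation: Folding, assembly and peptide loading of class I MHC had 12 of 25 higher and 0 lower (adjusted p = 2.67e-16), with Tap1 and H2-K1 leading. Among the lower sets, Mitotic Prometaphase had 5 of 99 genes lower and 0 higher (adjusted p = 0.00219), with Nsl1, a kinetochore gene whose log2 fold change was -1.0 (adjusted p = 0.092 without control 1 and 0.206 without control 2), and Aurkb leading. With an estimated correlation 0 sets were called, the smallest adjusted p was 0.995 and 19 had an unadjusted p under 0.05; fry called 0, with 163 under 0.05 unadjusted. Without genes of chromosomes 4 and 8, camera called 33 sets, 30 higher and 3 lower. The balance of directions depended on the library left out: camera called 43 higher and 37 lower without control 1, 85 and 13 without control 2, 44 and 75 without UBXN9 1, and 104 and 19 without UBXN9 2.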

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

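The tests of unannotated loci, of immune cells and of gene dosage for the interferon genes were chosen only after the results they bear on had been seen.

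Loci outside the annotation, which the report leaves out and an alternative fit adds, took more of the counts in the UBXN9 libraries. Their share was 0.307% and 0.302% in the controls, 0.381% in UBXN9 1 and 0.535% in UBXN9 2, and 24 of 152 tested loci were higher and 4 lower. A high value in 1 library alone is argued against by the 0.381% of the lower UBXN9 library, which exceeds the controls by more than 3 times the difference between them; a first test of this was replaced because its outcome was fixed by the calling of the loci. Carried-over ribosomal RNA remains open as a candidate explanation: 7 of the 24 higher loci, holding 93.5% of their counts, kept their ratio to the ribosomal RNA gene CT010467.1 within an SD of 0.25 on the log2 scale over the 4 libraries, against 3.3% of the counts of annotated genes that rose. Sharing of reads between near-identical copies cannot be told apart from other causes, since the SD of the log2 ratio between the UBXN9 libraries was 0.363, against a median of 0.358 in random gene sets whose own spread was 0.172. No biological explanation was tested.

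Genes of chromosomes 4 and 8 were shifted upward as a whole, outside the genes that changed by 1.21-fold and 1.25-fold against the other autosomes. A trend with GC content or transcript length is argued against, since after its removal the lower of the 2 medians was 0.224, above the 0.0903 of chromosome 5, the highest of the others. Extra copies of both chromosomes in the UBXN9-overexpressing cells remain a candidate explanation: 96.4% of 28 windows along them lay above the median of the other autosomes, against 55% of 209 windows elsewhere. Chromosomes 4 and 8 were picked for their shift in these same data, which largely set this share in advance. The windows of chromosome 5, counted among those elsewhere, also all lay above that median, with values from -0.0236 to 0.333. Meeting this criterion is therefore not particular to chromosomes 4 and 8. Extra copies could have arisen in the selection of the cells or be linked to UBXN9, and the design cannot separate these.

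Interferon-stimulated and antigen presentation genes were called higher as lists by camera, but not with an estimated correlation (adjusted p = 0.261 for both). Fry also called both (adjusted p = 0.0134 and 0.0372), but it does not compare a list with other genes. Immune cells in the cultures are argued against, since 7 abundant immune-cell transcripts summed to 5.53 CPM in UBXN9 1 and 0.452 CPM in UBXN9 2. Dosage of the members themselves is argued against for the 70 members outside chromosomes 4 and 8. Their median log2 fold change was 2.48, with 64 higher. These values cannot decide whether extra copies of genes on chromosomes 4 and 8 acted on genes elsewhere. The expression construct or its delivery, rather than UBXN9, may be the cause and cannot be told apart from it, since the labels name 0 libraries given the delivery without UBXN9. An effect of UBXN9 itself therefore stays a hypothesis.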

How the results depend on the processing

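The crossed replicate block, the unannotated loci and the fit without chromosomes 4 and 8 were chosen after seeing the data. None of the 984 changed genes reversed its sign in the alternative fits that tested it. That was largely set by the calls, since in all of them both UBXN9 libraries lay on the same side of both controls. The Aspscr1 log2 fold change stayed between 1.738 and 2.066 and past the threshold throughout. Changed genes numbered 732 to 1249 across the scalings, the strict filter, the other tools, the robust prior, the replicate block (932, 811 of them shared), the added loci and the fit without chromosomes 4 and 8; they numbered 788 with a 2-fold threshold. Without a filter 1827 genes changed, 1144 higher and 683 lower, with 22729 tested. At an adjusted p of 0.01 there were 398, 310 higher and 88 lower, from the stricter threshold. With the crossed replicate block there were 3137, 1776 higher and 1361 lower. This block joins control 1 with UBXN9 2 and control 2 with UBXN9 1. Across genes, deviations from the group mean correlated at 0.373 in these pairs and at -0.373 between libraries of the same number. With 2 libraries per group the deviations mirror each other, so each of these values fixes the other. The block thus takes up a difference that the joined libraries share, and no separate test of the cause was run.

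With 1 library left out, changed genes ranged from 508 to 2782, higher ones from 373 to 1611 and lower ones from 135 to 1318; the removal of a control lowered and that of a UBXN9 library raised the count, and the cause was not tested. Lists called lower ranged from 1 to 4 and Reactome sets from 80 to 123, the higher ones from 43 to 104 and the lower ones from 13 to 75. With an estimated correlation 0 lists were higher and 0 lower, with 5 lists under 0.05 unadjusted and a smallest adjusted p of 0.261, and 0 Reactome sets were called. Fry called 10 lists higher and 1 lower, 9 of them among those camera called. Its smallest adjusted p was 0.0134 over the lists and 0.0788 over the Reactome sets, of which it called 0. Without chromosomes 4 and 8, 33 Reactome sets were called, with fewer genes tested. The causes of the set results were not otherwise tested.

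Over 131 named genes, 94 of them called, 1854 of 2037 values kept direction and side of the threshold (5 of them, not called by edgeR, had no adjusted p by DESeq2), 80 lost their call, 94 gained one and 9 reversed; none of the reversed values passed, and the cause was not tested. The Dis3 log2 fold change was 0.04 without control 1, -0.2565 without UBXN9 2 and 0.1252 without UBXN9 1. The Mtrex log2 fold change was 0.02668 without chromosomes 4 and 8, 0.06413 without control 1, -0.2398 without UBXN9 1 and 0.1881 without UBXN9 2. The Hras log2 fold change was 0.0195 without chromosomes 4 and 8, 0.1818 without control 2, -0.319 without UBXN9 1 and 0.2325 without UBXN9 2. The Csf1r log2 fold change was -0.8353 without UBXN9 1 and 2.35 without UBXN9 2. In simulations at this depth 44.4% of genes changed by 1 on the log2 scale were found, so smaller changes can be missed.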

Other observations

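Pax5, a transcription factor of B cells, and Ighm, an immunoglobulin heavy chain gene, were singled out after their values were seen. Ighm rose from 0.133 to 3.19 CPM in the mean, with a log2 fold change of 4.60 and an adjusted p of 0.00733 by edgeR, and had 73 counts in each UBXN9 library. Ebf1, another transcription factor of B cells, had a log2 fold change of -0.39 and did not pass.

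The noncoding test was chosen only after the result was seen, and its poly-A test before. A hypothesis from the study's title is that RNA exosome substrates accumulate in UBXN9-overexpressing cells. Of 1258 tested noncoding genes (long noncoding, antisense and pseudogene RNA), 40 were higher and 11 lower, and their median log2 fold change was 0.047, above 98.46% of 10000 random lists of protein-coding genes of matched expression. The median was 0.014 in UBXN9 1 and 0.095 in UBXN9 2 against the controls, and -0.103 for control 2 against control 1, further from 0 than the shift between the groups. Outside chromosomes 4 and 8 it was 0.033, against -0.0437 for all coding genes there. These coding genes were not matched in expression, so the 2 values cannot decide whether the excess holds outside those chromosomes. Less complete poly-A selection was tested by the ratio of UBXN9 2, which held more 7SK RNA, to UBXN9 1. The noncoding median of this ratio was 0.0611. It lay above 4.32% of random lists of matched coding genes, most of them between 0.0626 and 0.13. This argues against less complete selection as a source of more noncoding RNA in UBXN9 2 than in UBXN9 1. Both UBXN9 libraries held more ribosomal RNA than the controls, and this ratio cannot decide on incomplete selection shared by both. By class, the median log2 fold change between the groups was 0.0107 for 259 long intergenic, 0.0388 for 245 antisense and -0.041 for 174 processed-transcript RNAs. It was 0.112 for 280 processed and 0.307 for 29 unprocessed pseudogenes, whose reads may be shared with their parent genes. No class was tested alone. Reduced RNA decay remains a hypothesis for the 0.047, which pools classes with unlike medians. Chance differences between libraries are not excluded, and RNA decay itself was not measured.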
